A study of Danio rerio with 4 samples.

How the data were processed

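Open chromatin was measured in nuclei of zebrafish embryos collected 6 h after fertilisation, with a 10x Genomics droplet kit that reads RNA and open chromatin from the same nuclei and a target of 10000 cells, per the submitters' protocol. Per the file headers, the authors made the fragment table with Cell Ranger ARC 2.0.0 on GRCz11; the submitters' processing notes also name Cell Ranger 6.1.2. The release of the annotation was not stated. Each record of the deposited table is a distinct fragment with its sequence, start, end and barcode, and a count of the read pairs that showed it, with duplicates joined and no normalization. The counts are whole numbers from 1 to 24 (mean 1.84), and 52.8% of fragments were seen in 1 read pair. Whether the ends were moved for the offset of the transposase was not stated. Barcodes had not been filtered to cells. The same text on culture and treatment of explants stands beside all 4 samples, and it was not taken to hold for the embryos. The RNA samples of the explants and of the embryos were not analysed here.

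Several choices were made before the data were examined: the barcode filter, the removal of doublets, the clustering and its resolution, the use of separate chromosomes for clustering and for values, the intervals, most alternatives and a rule for the genes to be named. That rule rested on gene positions. The gene tables at hand were for another build of the genome than GRCz11, so no position was moved between builds and no gene was placed. The planned enrichment at transcription start sites, the values at listed genes, the naming of clusters by marker genes, the comparisons of prechordal plate with endoderm and of mesendoderm with ectoderm, the co-accessibility of listed loci, the distal elements near listed genes and the search for transcription factor motifs were therefore not run. Tiles near listed genes were likewise not kept out of the clustering. The rule was carried over to accessible elements, after the files had been looked at for their format. For each family it took the 10 elements with the highest lower bound of the log2 ratio and the 5 with the lowest upper bound, among elements of even-numbered chromosomes with at least 30 fragments. For each cluster within a family it took the 3 highest. For each window the ratio was also computed without the element that held most fragments of the family in the choosing nuclei, which was added after the results had been seen. Windows, bins, tiles and the widest elements named in the text are the extremes of their tables.

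Barcodes with at least 2000 fragments on the 25 nuclear chromosomes were taken (4858). In place of the planned filter on transcription start sites, barcodes whose share of insertions in elements was below 0.5 times the median of 44.7% were left out (37). Doublets were scored by adding simulated sums of pairs of nuclei and counting those among the 50 nearest neighbours in 10 singular vectors. The highest scores were removed at 0.8% per 1000 barcodes, which took 186 barcodes (3.86%) with a median of 34072 fragments. That rate set the number removed, so the 3.86% is not an estimate of the share of doublets. A first version of this score found fewer of the doublets in simulated data and was replaced after a first clustering had been seen. The 4635 nuclei kept ranged from 2003 to 123334 fragments.

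For the clustering, 1 kb tiles of odd-numbered chromosomes were made binary, the 50000 seen in most nuclei were weighted by term frequency and inverse document frequency, and 30 singular vectors were computed. The 1 vector that correlated with log depth at over 0.5 in size was dropped, and a graph of 20 nearest neighbours was clustered by the Leiden method at resolution 1.0. Clusters were joined into families by average linkage on the correlation of their log2 levels (fragments per 1000000 plus 1, centred on the mean of the clusters) over elements of odd-numbered chromosomes with at least 300 fragments, at a correlation of 0.4. Clusters 1 and 10 correlated at 0.40 there and clusters 2 and 8 at 0.40 as well, so the boundaries of families IV and V lie near that limit. This step and its limit were chosen after the clusters had been seen. Elements were runs of adjoining 500 bp tiles in the kept nuclei pooled. Each tile held at least 5 times the median of the 201 tiles around it or of all tiles (27 insertions), whichever was larger.

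Values are fragments with at least 1 end in an element, per 1000000 nuclear fragments of the family (FPM), with exact Poisson intervals. Fragments replaced insertions as the unit after the first results had been seen, since the 2 ends of a fragment are not independent and made intervals too narrow. Medians over nuclei carry order-statistic intervals where one is given. Ratios carry exact conditional binomial intervals and shares Clopper-Pearson intervals, all at 95%. Nuclei of 1 embryo library are not replicates, so no test between groups was made and no p-value is given. Named elements and windows were chosen in 1 of 2 sets of nuclei, split by barcode, and measured in the other. Summaries over elements used those of even-numbered chromosomes with at least 300 fragments in the compared nuclei and at least 50 expected in the smaller group, which left 15620 elements for families I to III, 1995 for family IV and 66 for family V. The windows of 100 kb held at least 5 elements and at least 500 fragments. A level of 0 fragments was set to a floor of 3 counts over the group.

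The steps were tested on simulated data. From 1500 simulated nuclei of 4 profiles the clustering found 4 clusters, with 99.9% of nuclei in the cluster of their own profile. These profiles were the means of families I to IV from the same clustering, so their recovery does not test whether the families exist. Family V was not simulated. Of 60 simulated doublets, 61.7% were among as many of the highest scores. From 1000 simulated nuclei of 1 profile it found 15 clusters of at least 20 nuclei. In simulated counts with 200 changed elements among 46813, a fold of 1.5 was recovered at a median of 1.47 to 1.54 and a fold of 3.0 at 3.00 to 3.03. The intervals held the true value for 92.0 to 98.0% of changed elements and for 95.6 to 96.0% of the others. These counts were drawn with Poisson error only, so coverage was not tested for fragments that gather in single nuclei.

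The alternatives were a fragment minimum of 1000 or 5000, no removal of doublets, clustering on even-numbered chromosomes, resolutions of 0.5 and 2.0, tiles of 5 kb, fragments under 120 bp only and fragments seen in at least 2 read pairs only. Added after the data had been seen were no element share filter, leaving out barcodes over 40000 fragments and scaling by fragments in elements. So were elements at 10 times the local or the genome median, whichever was larger, and insertions in place of fragments. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0, pandas 2.3.3, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.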

Results

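The series examined how the level of Nodal, a secreted signal that induces mesoderm and endoderm, parts mesendoderm cells into separate fates in the zebrafish, and whether chromatin takes part in that parting. It holds 4 samples of age 6 h after fertilisation, 1 in each of 4 groups. In 2 of them single-cell RNA was measured in explants of the animal pole made to carry Nodal signal, with embryos mutant for the Nodal antagonist lft1 in the first and embryos depleted of the Nodal ligand ndr1 in the second. The other 2 are the RNA and the open-chromatin parts of a joint assay on nuclei of whole embryos, and the values below come from the open-chromatin library of those embryos (1 library, no replicate). In that assay a transposase cuts accessible DNA and leaves fragments that carry the barcode of their nucleus. The library held 98137813 distinct fragments from 180360800 read pairs under 444126 barcodes, and 98.6% of the fragments lay on the 25 nuclear chromosomes. A set of 4635 nuclei was kept, with a median of 16438 fragments each (quartiles 10201 and 23205), and together they held 82416245 fragments, or 85.2% of those on nuclear chromosomes. Positions are on GRCz11, given as chromosome:start-end and counted from 1. Intervals are 95% intervals that cover counting error only.

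The first comparison asked where along the genome open chromatin lay in the embryo as a whole. The long arm of chromosome 4 stood apart from every other chromosome. Beyond 30 Mb on chromosome 4 there were 58.6 insertions (fragment ends) per kb, against 145 on the first 30 Mb of the same chromosome and 113 (chromosome 9) to 136 (chromosome 23) on the other 24 chromosomes. The arm carried 42.2 accessible elements per Mb, against 95.2 on the first 30 Mb and 70.0 to 85.4 on the other chromosomes. This count is not separate from the insertion density, since the threshold for elements never fell below a multiple of the genome median per tile. That median was 27 insertions, against 17 in the non-empty tiles of the arm. How much of the low element count follows from the threshold was not tested. Of the 20 sparsest among 1336 1 Mb bins, 14 lay on this arm, with the lowest at 4:38000001-39000000 (16.8 insertions per kb) and 4:37000001-38000000 (16.9 per kb). The densest bins were 25:35000001-36000000 (404 per kb, of which 71.9% fell in elements), 4:1-1000000 (366 per kb), 22:1-1000000 (341 per kb) and 7:6000001-7000000 (341 per kb), against a median bin of 116 per kb.

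**Figure D1:**
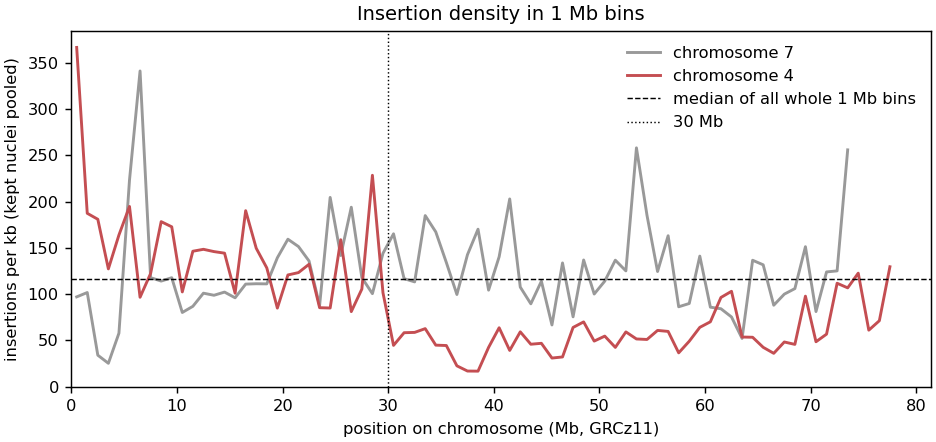
Insertions per kb in 1 Mb bins along chromosome 4 (red) and, for comparison, chromosome 7 (grey), in the kept nuclei pooled; the x axis is the position in Mb. Beyond 30 Mb (dotted line) most bins of chromosome 4 lay below the median bin of 116 insertions per kb (dashed line), and the lowest held 16.8.

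Accessible elements were runs of 500 bp tiles with at least 5 times the local or the genome median of insertions, whichever was larger. There were 101237 of them, covering 5.55% of the tiled genome and taking 44.5% of all insertions, with a median of 342 insertions each. The tiles with most insertions were 17:53384501-53385000, with 37906 insertions and a fragment in 88.3% of nuclei, and 2:56482001-56482500, with 33343 insertions and a fragment in 87.5% of nuclei. They held 18954 fragments in 4092 nuclei and 19919 fragments in 4056 nuclei, at 566 and 1076 times the local median. Whether these tiles lie in repeated sequence was not tested. The widest element spanned 14500 bp at 8:35044501-35059000, and 514 elements were at least 3 kb wide. Fragment lengths showed a sub-nucleosomal mode at 48 bp and a mono-nucleosomal mode at 163 bp after smoothing over 11 bp. These modes belong to the smoothed curve and are not the commonest single lengths. Unsmoothed, 382327 fragments measured 48 bp against 815822 at 44 bp, and 256895 measured 163 bp against 586394 at 159 bp. Fragments under 120 bp made up 52.1% of those in elements and 33.7% of those outside them.

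The second comparison asked how many kinds of nuclei the embryo held by accessibility alone. Clustering on odd-numbered chromosomes gave 10 clusters, and their profiles over elements joined into 5 families, numbered by size. Family I (clusters 2, 3 and 5) held 1989 nuclei, or 42.9% (Clopper-Pearson interval 41.5 to 44.4%). Family II (clusters 1 and 6) held 1298 nuclei (28.0%, interval 26.7 to 29.3%) and family III (clusters 4, 7 and 9) held 1015 (21.9%, interval 20.7 to 23.1%). Family IV (cluster 8) and family V (cluster 10) were small, with 259 nuclei (5.59%, interval 4.94 to 6.29%) and 74 nuclei (1.6%, interval 1.26 to 2.0%).

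The same clusters were joined again by their elements on even-numbered chromosomes, which took no part in the clustering. At the same limit of 0.4 this gave the same 5 families. The step grouped clusters already made and found none afresh, so it is not an independent finding of the families. Family IV stayed apart from family I only narrowly, with correlations of 0.393 to 0.403 against that limit. On these chromosomes family III was the most distinct, since its 3 clusters correlated with each other at 0.884 to 0.912 over elements and with every cluster of the other families at −0.671 to −0.489. Clusters within family I correlated at 0.645 to 0.804, and clusters 1 and 6 of family II at 0.62. Family IV lay closest to family I (0.393 to 0.403) and family V closest to cluster 1 of family II (0.377), while families IV and V correlated with each other at 0.273. These correlations are across elements of 1 library, centred on the mean of the clusters, and elements are not independent replicates. They were not corrected for counting error, which weakens correlations most in shallow clusters. Cluster 8 (family IV) held 2857808 fragments and cluster 10 (family V) 873146, against at least 5326666 in every other cluster. Whether families IV and V would stay apart from families I and II at equal depth was not tested. Simulated nuclei of a single profile also split into 15 clusters under the same settings, so the number of clusters does not count kinds of nuclei, and the families are described by their elements on even-numbered chromosomes. Family V was not found as a family of its own at a clustering resolution of 0.5, with a minimum of 5000 fragments, or without barcodes over 40000 fragments.

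**Figure D2:**
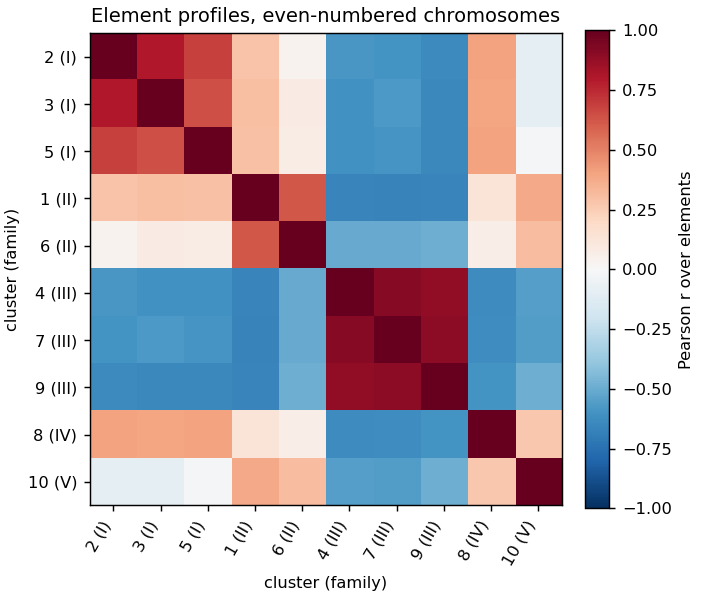
Pearson correlation between clusters (both axes, family in brackets) of their log2 levels over elements of even-numbered chromosomes, each centred on the mean of the 10 clusters. Clusters 4, 7 and 9 of family III correlate at 0.884 to 0.912 with each other and negatively with every other cluster.

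The families differed in depth, in the share of insertions in elements and in mitochondrial fragments. Nuclei of family III held a median of 22724 fragments, with a median of 40.4% of insertions in elements, against 15679 fragments and 45.6% in family I and 16542 fragments and 45.6% in family II. Families IV and V were shallower, at 9163 and 10319 fragments, with 49.6% and 51.7% in elements. At 15000 to 25000 fragments the median shares were 46.35% in family IV (56 nuclei) and 47.14% in family V (13 nuclei). Those of families I and II were 45.44% and 45.65% there. At 10000 to 20000 fragments the medians were 48.03% (IV, 78 nuclei) and 53.39% (V, 30 nuclei), against 45.52% (I) and 45.82% (II). The size of the excess in families IV and V thus depended on the depth compared. Mitochondrial fragments per 10000 nuclear fragments were 33.3 (Poisson interval 32.6 to 34.0) in family IV and 22.3 (21.4 to 23.4) in family V. Family III had 12.4 (12.2 to 12.5), family I 7.83 (7.73 to 7.93) and family II 7.23 (7.12 to 7.34). Fragments under 120 bp made up 44.3% of the fragments of family III and 39.3 to 41.0% of those of the other families.

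**Figure D3:**
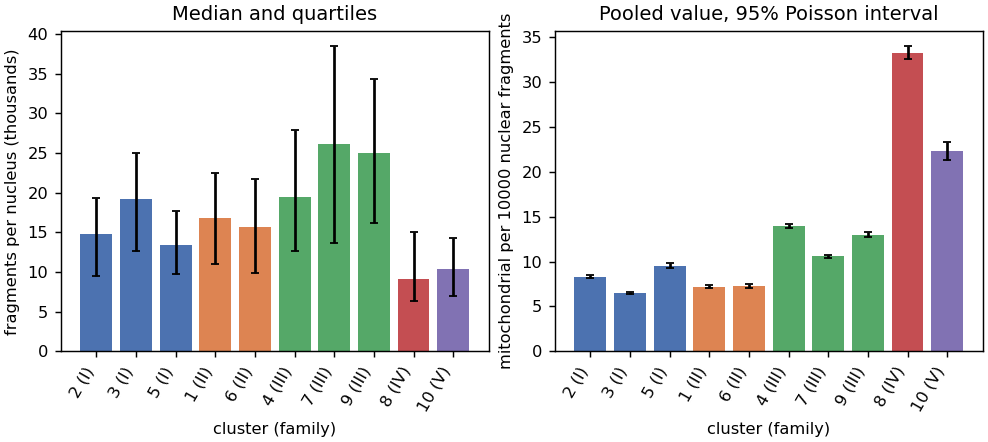
Left, fragments per nucleus (in units of 1000) in each cluster, with bars at the median and lines at the quartiles; right, mitochondrial fragments per 10000 nuclear fragments with 95% Poisson intervals that cover counting error only. Cluster 8 (family IV) had 33.3 and cluster 10 (family V) 22.3 mitochondrial fragments, against 12.4 in family III as a whole.

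The third comparison asked which elements set the families apart, with each element chosen in 1 part of the nuclei and measured in the others. Family III had the sharpest differences. The element 12:48576001-48576500 gave 9.56 FPM (fragments per 1000000 nuclear fragments of the group) in family III against 0.14 in all other nuclei, a ratio of 70.4 (26.8 to 262). At 10:21266501-21267000 the ratio was 45.9 (24.5 to 97.1) and at 12:33427001-33427500 it was 52.1 (19.7 to 195). The named element with most fragments in family III was a stretch of 5500 bp at 6:39308001-39313500, with 148 FPM in family III and 3.94 in the rest, a ratio of 37.5 (31.1 to 45.6). All 10 elements chosen as high in family III kept a ratio whose interval lay above 1 in the measuring nuclei, from 26.2 to 70.4.

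Family III also lacked elements that the other families shared. At 24:13995501-13996000 it had 1.96 FPM, 14.9-fold lower than the other nuclei, while family I had 27.0, family II 30.7, family IV 33.9 and family V 52.6. The fold was 15.3 at 2:53525501-53526000, 12.4 at 22:20678501-20679000, 12.4 at 2:28184001-28185000 and 8.92 at 18:20347001-20347500. Over the 15620 elements of even-numbered chromosomes with at least 300 fragments, the log2 ratio of family III to the rest ran from −2.14 at the 5th percentile to 2.10 at the 95th, around a median of −0.41. The standard deviation of these ratios was 1.23, against 0.15 from counting error alone, and the values in the 2 sets of nuclei correlated at 0.965.

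Elements chosen as high in family II had ratios of 9.67 to 18.5 in the measuring nuclei. The largest ratio in family II was 18.5 (12.0 to 29.8) at 4:5705001-5705500, with 14.0 FPM. It was 15.0 (8.88 to 26.9) at 22:29819501-29820000, 13.9 (9.76 to 20.3) at 4:22626501-22627000 and 13.2 (8.93 to 20.2) at 4:8367501-8368000. Family V shared several of these: at 2:35671001-35672000 it had 61.7 FPM (40.7 to 89.8) against 28.9 in family II, 2.68 in family I and 1.20 in family III.

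Elements high in family I had smaller ratios than those named for families II and III. The largest were 7.48 (5.38 to 10.6) at 20:33330501-33331000, 6.84 (4.94 to 9.65) at 6:32206501-32207000 and 6.51 (4.47 to 9.72) at 6:36481001-36481500. All 10 elements chosen as high in family I kept an interval above 1, from 3.92 to 7.48. Family IV had similar levels at several of them, with 8.31 FPM (4.42 to 14.2) at 6:36481001-36481500 against 8.66 in family I, 1.54 in family II and 0.30 in family III. The log2 ratio of family I to family II had a standard deviation of 0.53 over 10482 elements, against 1.27 for family I to family III and 1.32 for family II to family III. Family I was 25.3-fold lower than the rest at 18:45504001-45504500, with 3 fragments against 122 (log2 ratio −4.66, interval −6.96 to −3.08). Most elements chosen as low in families I and II were high in family III. At 8:31285501-31286000 family II had 0 fragments against 128 in the rest, 14.9-fold lower with the floor of 3 counts (lower bound of the interval 11.9). Family III had 8.88 FPM there, against 0.55 in family I.

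Families IV and V shared elements with far higher levels than in the larger families. At 20:55168001-55169000 family IV had 45.4 FPM (35.4 to 57.2) and family V 59.4 (38.8 to 87.1), against 1.83 in family I, 1.27 in family II and 1.20 in family III. The ratio of family IV to all other nuclei there was 21.7 (15.6 to 30.1). At 4:55759001-55761000, on the long arm of chromosome 4, the levels were 83.1 (69.4 to 98.7) in family IV and 80.02 (55.7 to 111) in family V, against 12.1 in family I and 7.08 in family III. The ratio of family IV was 9.66 (5.30 to 16.9) at 20:55166501-55167000. This element lies beside 20:55168001-55169000, and both are near the end of chromosome 20, which spans 55.2 Mb here. At 20:43994501-43995500 the ratio was 4.42 (2.57 to 7.23), with 12.1 FPM in family IV and 0.0 (0.0 to 8.43) in family V. Whether any of these elements lie in repeated sequence was not tested. The other 6 elements chosen as high in family IV had intervals that included 1 in the measuring nuclei; family IV held 2857808 fragments in all. Elements chosen as low in family IV were mostly high in family III, such as 24:38670501-38671500 with 0 fragments in family IV, 1.83 FPM in family I and 41.7 in family III. Both families had the highest levels of mitochondrial fragments.

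**Figure D4:**
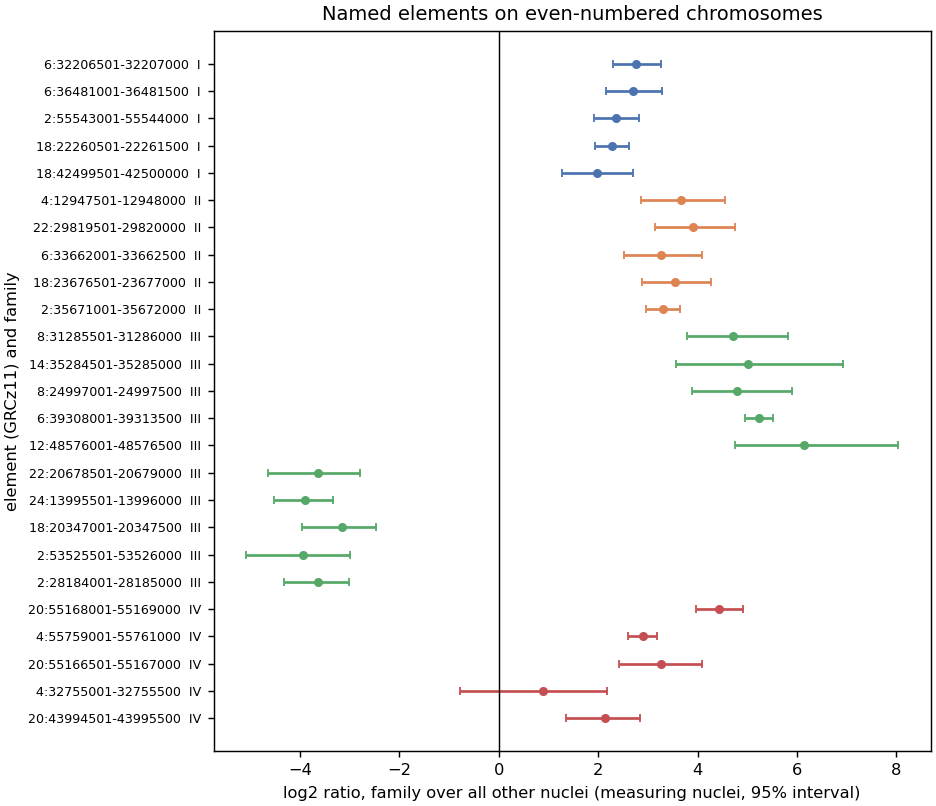
Log2 ratio of fragments in a family over all other nuclei for named elements of even-numbered chromosomes, with 95% conditional binomial intervals that cover counting error only. Elements were chosen in other nuclei than those plotted; those of family III reach 70.4-fold, and 1 of the 5 shown for family IV has an interval that includes 0.

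Within families the clusters differed less than families I to III did from each other, and most in family II. The log2 ratio of a cluster to the rest of its family had a standard deviation of 0.21 to 0.31 over elements, against 0.13 to 0.18 from counting error. The values in the 2 sets of nuclei correlated at 0.571 in family II and at 0.152 to 0.43 in families I and III. In family II, cluster 6 was 6.13-fold (3.46 to 11.3) above cluster 1 at 24:349501-350500, and cluster 1 was 4.64-fold (2.43 to 9.92) above cluster 6 at 4:1608501-1609500. Cluster 1 was also 3.70-fold (1.33 to 14.3) higher at 2:46414501-46415500 and 2.59-fold (1.36 to 5.41) at 24:28571001-28572000. Cluster 6 was 3.34-fold (1.35 to 8.50) higher at 16:3003001-3003500 and 2.57-fold (0.96 to 6.87) at 10:5911001-5911500. In family I, cluster 5 was 2.91-fold (1.82 to 4.62) above the others at 6:33501-34000 and 2.74-fold (1.70 to 4.38) at 22:36251501-36253500. Most other elements chosen within families shrank towards a ratio of 1, and 14:46398501-46399500, chosen as high in cluster 4, had a log2 ratio of −1.79 (−3.79 to −0.24) when measured.

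The fourth comparison asked whether neighbouring elements changed together between families. The ratio of family III over all elements of a window of 100 kb was 9.47 (8.13 to 11.1) at 8:6500001-6600000 and 8.75 (7.69 to 9.99) at 6:54700001-54800000. Without the element that held most family III fragments, the ratios of these windows were 8.51 (7.14 to 10.2) and 10.6 (9.07 to 12.5). At 6:39300001-39400000 the ratio was 9.53 (8.79 to 10.4) over 12 elements and 4.19 (3.79 to 4.63) without the element 6:39308001-39313500. The first windows by rank in the choosing nuclei had 3.70 (3.28 to 4.17) at 24:27600001-27700000 for family I, 3.62 (3.21 to 4.08) at 16:15400001-15500000 for family II and 2.59 (2.07 to 3.20) at 10:12000001-12100000 for family IV. Without their strongest element these were 2.61 (2.22 to 3.07), 2.75 (2.39 to 3.16) and 2.17 (1.40 to 3.24). The next window of family IV, 18:37900001-38000000, had 1.29 (0.86 to 1.86), and those named after it had 1.61 to 1.94. The median log2 ratio of family IV over elements was itself 0.56. In families I to III likeness between elements fell off with distance. The log2 ratios of family III for elements under 5 kb apart correlated at 0.48, those 100 to 200 kb apart at 0.034 and those 2 to 5 Mb apart at −0.003. The matching values under 5 kb and at 100 to 200 kb were 0.389 and 0.02 in family I, and 0.333 and 0.014 in family II. In family IV they were 0.385 (115 pairs) and 0.034 (928 pairs), with 0.659 at 5 to 20 kb (343 pairs) and 0.488 at 20 to 50 kb (430 pairs).

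**Figure D5:**
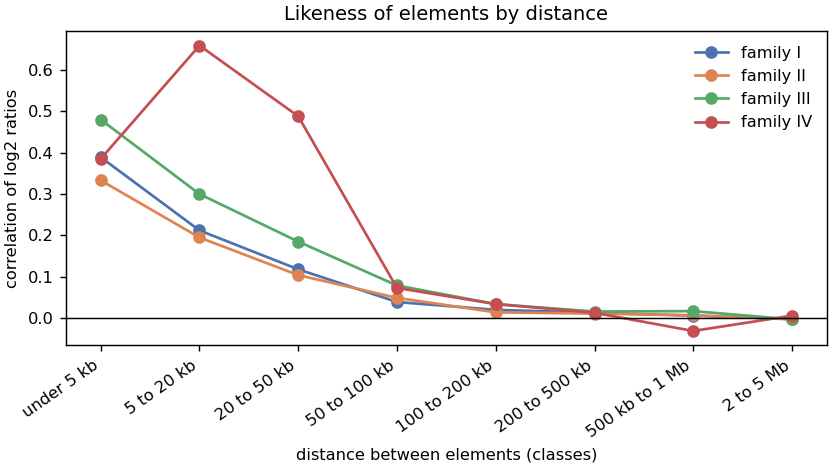
Correlation of the log2 ratios (family over all other nuclei) of pairs of elements on even-numbered chromosomes, by distance class on the x axis, for families I to IV. Family III falls from 0.48 under 5 kb to 0.034 at 100 to 200 kb, and family IV has 0.385 (115 pairs), 0.659 (343 pairs) and 0.488 (430 pairs) in the first 3 classes.

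Shares of fragments on whole chromosomes differed little between families. They pool many elements with the fragments outside them, so they were bound to vary less than single elements chosen as extremes. The long arm of chromosome 4 took 1.76% of the fragments of family I, 1.69% of family II, 1.65% of family III, 1.73% of family IV and 1.68% of family V. Chromosome 7 took 5.93% in family IV and 5.52% in family III, and chromosome 8 took 4.25% in family III and 3.96% in family V. Chromosome 12 took 3.57% in family III and 3.36% in family I.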

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

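Of the tests in this part, the one on mitochondrial fragments per nucleus was chosen only after the result had been seen, and the patterns had been noticed in the same library first. The design holds 1 library of embryos and no group that parts the families of nuclei, so no biological explanation was tested for any pattern here.

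The comparisons of elements, windows and chromosomes left out part of the library. In the kept nuclei this part came to 709694 fragments on unplaced sequences and 83160 mitochondrial fragments, and no control sample gives a level to set them against.

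The long arm of chromosome 4 beyond 30 Mb had 58.6 insertions per kb against at least 113 on each of the other 24 chromosomes. Stretches with no placed fragment at all do not account for it, since tiles of 500 bp with at least 1 insertion had a median of 17 insertions there and at least 27 on each other chromosome. Empty tiles were more frequent too, at 18.3% against 1.78 to 5.45%. A loss of fragments that could not be placed in repeated sequence may contribute: fragments under 80 bp, which are harder to place, made up 17.6% outside elements, below the lowest value of 24.3% on the other chromosomes. Denser packing of the arm was not tested and stays open.

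Nuclei of family III held more fragments (median 22724) and a lower share of insertions in elements (40.4%) than those of families I and II. Whether more barcodes of family III hold a pair of nuclei could not be decided: at 15000 to 25000 fragments the median was 16.5 places per nucleus where 3 or more fragments overlap, and up to 23 in the other families, but these medians rose with the element share of the 5 families at that depth (40.9% in family III to 47.1% in family V, rank correlation 1.0). The number of fragments as such does not account for the share: among nuclei with 10000 to 20000 fragments the median share was 41.3% in 258 nuclei of family III, below the lower quartile of 43.4% in 956 nuclei of family I. Differences in how well nuclei of each kind survived preparation were not tested.

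Family IV had 33.3 mitochondrial fragments per 10000 nuclear fragments against 7.83 in family I. Low depth does not explain it, since among nuclei with 5000 to 10000 fragments the levels were 64.9 in family IV (106 nuclei) and 9.47 in family I (275 nuclei), a ratio of 6.85 (6.51 to 7.22). These levels pool the fragments of all nuclei, so nuclei rich in mitochondrial fragments weigh more, and the interval leaves out the spread between nuclei. Free DNA taken up evenly by all barcodes is argued against as well, since at the same depth the median was 20.5 mitochondrial fragments per nucleus in family IV (interval of the median over nuclei 17.0 to 27.0) and 4.0 in family I (3.0 to 6.0). Uneven uptake stays open. A share of 2.57% from barcodes of 50 to 500 fragments would bring the excess over all depths (33.3 against 7.83). The larger excess at 5000 to 10000 fragments would need a larger share, which was not computed. A share of 2.57% could raise the correlation of family IV with these barcodes over elements only to 0.015, so the measured −0.243 decides nothing. Damaged nuclei with adhering mitochondria were not tested.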

How the results depend on the processing

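No paired analysis was possible because each group of the series has 1 sample, so no samples pair as replicates across groups; the RNA of the embryo nuclei, which the assay pairs with their chromatin nucleus by nucleus, was not analysed here. No direction of a named ratio whose interval excluded a log2 ratio of 0 reversed under any alternative that was run. The number of nuclei was 4958 and 4201 with minimums of 1000 and 5000 fragments, 4821 without removal of doublets and 4669 without the element share filter. Between 95.5% and 97.8% of shared nuclei fell in the same family under the 8 alternatives to the clustering.

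Several values moved by more than their interval, and the cause was not tested. At resolution 0.5 there were 5 clusters, with 6.45% of nuclei in family IV and 0.0% in family V. At resolution 2.0 there were 16 clusters, with 2.01% in family V. Clustering on even-numbered chromosomes gave 26.4% in family II, and tiles of 5 kb gave 1.21% in family V. With a minimum of 5000 fragments, families I, II, IV and V held 45.1%, 26.2%, 6.55% and 0.0%. Without barcodes over 40000 fragments, an alternative chosen after the data had been seen, families I, III, IV and V held 45.0%, 19.5%, 7.43% and 0.0%. Of the named elements, 16 of 87 moved with fragments under 120 bp only (median shift 0.37 in log2, largest 2.38), 3 of 89 with fragments in at least 2 read pairs, and 1 of 56 each at resolution 0.5, with the minimum of 5000 fragments and without barcodes over 40000 fragments. None moved in this sense under the other 7 alternatives that gave values for them. The largest log2 shifts there were still 1.52 with clustering on even-numbered chromosomes, 1.25 without removal of doublets and 1.13 with tiles of 5 kb. The named elements lie on even-numbered chromosomes, so with clustering on those chromosomes their values were not separate from the making of the groups. Scaling by fragments in elements, added later, was among the 7. It took the median log2 ratio of elements from 0.14 to 0.08 in family I and from 0.07 to 0.02 in II. That median went from −0.41 to −0.26 in III, from 0.56 to 0.39 in IV and from 0.19 to −0.01 in V. Not run were the alternatives on transcription start sites, listed loci, the comparisons of named classes, co-accessibility and motifs, which needed gene positions or sequence on GRCz11. Depth limits families IV and V most, with 1995 and 66 elements of even-numbered chromosomes deep enough for the summaries.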

Other observations

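No test in this part was chosen after its result had been seen, and the elements of family V below were chosen by the rule used for the other families. Family V, with 74 nuclei, had a window of 100 kb at 18:20300001-20400000 whose 11 elements together were 3.02-fold (2.47 to 3.66) above all other nuclei. At 22:36018501-36019000 family V had 22.9 FPM (10.96 to 42.04) against 8.79 in family II, 0.61 in family I and 0.38 in family III. At 4:297501-299000 it had 38.9 (22.6 to 62.2) against 25.5 in family II and 3.42 in family I. Of the 10 elements chosen as high in family V, 5 had intervals that included a ratio of 1 in the measuring nuclei, among them 14:37799501-37800000 with 0 fragments. Of the 5 chosen as low, 3 had such intervals, and 8:18830001-18831500 was 2.02-fold higher (1.04 to 3.56). The unplaced sequence with most fragments held 52672 of them, or 7.42% of those on unplaced sequences, at 5.61 per 10000 nuclear fragments in family III (5.52 to 5.71) 6.64 to 6.77 in families I, II and IV, and 7.2 in family V (6.65 to 7.79). Barcodes of 50 to 500 fragments had 1000 mitochondrial fragments per 10000 nuclear fragments, far above any family.

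Families IV and V may carry a shift of accessibility in common, on top of profiles like those of family I and family II. Over 3819 elements of even-numbered chromosomes with at least 1000 fragments, the log2 ratio of family IV to family I and that of family V to family II correlated at 0.526, while the ratio of family III to family II gave 0.05 against the first of these. This is a hypothesis found in the same library, and whether the shift comes from the state of these nuclei in the embryo or from their handling was not tested. Both families also had fewer fragments per nucleus and more mitochondrial fragments than families I and II.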
